A study of Mus musculus with 10 samples.

How the data were processed

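Gene expression was measured in epididymal white adipose tissue, the visceral fat pad next to the testis, of male mice on a C57/Bl6 background. The mice were 8 to 12 weeks old when a diet with 45 energy% of fat was started and were killed after 16 weeks. Per the labels, RNA of 3 ASC-/-, 3 Casp1-/- and 4 wild-type (WT) mice was used, with 1 array per mouse. Total RNA was copied with an oligo-dT primer carrying a T7 promoter, labelled with biotin and hybridised to Affymetrix HT_MG-430 PM arrays, which read transcripts mainly near their 3' ends.

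The deposited values are log2 signals made by the authors with RMA, per the submitters' processing notes, which name no version. RMA subtracts background, forces the same distribution onto every array and summarises the probes of a probe set on the log2 scale, so that a change in the total amount of RNA per cell leaves no trace and small changes near background are compressed. The values of the 10 arrays have medians from 4.29 to 4.36. The genome build behind the probe sets is not given in the sources used here. The number of arrays limits the precision, and no signal was given an interval of its own.

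The table holds 45141 probe sets. Of these, 104 are control probe sets, 28898 were paired with 1 gene symbol, 551 with several and 15692 with no symbol in the annotation used. Where a gene had more than 1 probe set, as 7180 genes did, the probe set with the highest mean over all 10 arrays stood for it, which left 17097 genes. No filter on dim genes was applied. The values of 23 control probe sets meant to bind nothing in mouse RNA gave the background. A table of gene order from the GRCm38.p6 assembly served only for names and for the order of neighbouring genes.

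Each gene was fitted with limma 3.58.1 in R 4.3.3, with 1 mean per genotype over all 10 arrays and the default empirical Bayes step (7 residual and 2.43 prior degrees of freedom). The 4 contrasts were ASC-/- minus WT, Casp1-/- minus WT, ASC-/- minus Casp1-/- and the mean of both null genotypes minus WT. Tests were two-sided, and genes with a Benjamini-Hochberg adjusted p under 0.05 over all genes tested are described as past the threshold. Errors are standard deviations over arrays (SD) or standard errors of the fitted difference (SE).

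There were 37 gene lists, covering immune and other cell types, adipocyte functions, metabolic pathways, stress responses and tissues that a dissected piece might include. Of 783 list entries, 685 matched a tested gene. Each list was tested with camera from limma at a preset correlation between genes of 0.01, and again with a correlation estimated from the data and with fry, with Benjamini-Hochberg adjustment over the lists of a contrast. Members were also adjusted over the list alone.

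The contrasts, tests, lists and the rule for naming genes were set before the data were examined. The rule took the targeted genes and Casp4, 12 fixed genes of adipose tissue and inflammation, 5 genes known to differ between mouse substrains or to be linked to them (Dock2, Nnt, Wdfy1, Ide and Entpd4), the 6 largest rises and 6 largest falls past the threshold without overlap between arrays, and up to 4 members of each list past the threshold that moved with it. Targeted and predicted genes were left out of the largest changes, and where none passed the 3 with the smallest p were taken. Genes named outside it are introduced as chosen after their values were seen. The 4 WT arrays serve both null genotypes, so the agreement between these was set beside 1000 simulations of unchanged groups against the same WT arrays and beside splits of the WT arrays.

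The alternatives chosen in advance were quantile normalization, centring each array on its median, leaving out the dimmest genes, means over probe sets, all probe sets, a trended and robust empirical Bayes step, array weights, fits of only the compared groups, the replicate number as a block, leaving out each array, leaving list members near the targets out, and 20 or 100 neighbours on each side. After the data had been seen, 5 were added. One used as a block the batch that the poly-A spike-in controls show, one used the 3' minus 5' signal of actin as a covariate, one used the mean of the macrophage markers as a covariate, and the last pair used only the arrays with low or only those with high spike-in signal. The macrophage covariate is itself an outcome, so only counts are given under it. The choice to leave out its values for single genes was made after they had been seen.

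The fit was tested on simulated data with the spread of these arrays, with noise drawn independently for each gene and no batch. Of 100 genes raised or lowered by 1 on the log2 scale, it found 77 in the Casp1-/- contrast and 85 in the ASC-/- contrast. Of 100 genes raised or lowered by 2, it found 99 and 95. In the Casp1-/- contrast 10 unchanged genes were called. The real arrays share structure across genes, so these rates need not hold for them.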

Results

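Adipose tissue of obese mice is rich in macrophages, and the inflammasome is a complex in which a sensor protein, the adaptor ASC (gene Pycard) and the protease caspase-1 (gene Casp1) together release active interleukin-1beta and interleukin-18. The series asked what the inflammasome does in diet-induced obesity. It compared epididymal fat of ASC-/- mice (n = 3), Casp1-/- mice (n = 3) and WT mice (n = 4) after 16 weeks on the high fat diet. All values below are log2 signals, and background lay at array medians of 2.91 to 3.15 with single control probe sets of up to 5.01. Where the mean of a group lay within that range the size of a change is uncertain, and levels are given in place of a fold. The first principal component held 50.5% of the variance. On it the Casp1-/- arrays lay lowest (-46.5 to -34.9). WT replicates 1 (-13.0) and 2 (-0.64) came next, then ASC-/- replicates 3 (6.40) and 2 (17.8). Highest were WT replicate 4 (25.3), ASC-/- replicate 1 (33.7) and WT replicate 3 (48.8). The mean of the pan-macrophage markers rose in nearly the same order, from 9.15 on Casp1-/- replicate 2 to 11.50 on WT replicate 3. This axis thus divided the WT arrays too. On the second component (17.4%) WT replicate 1 (-40.5) and ASC-/- replicate 1 (-29.2) stood apart from the other arrays (-0.69 to 13.2). The mean of 14 epididymis markers was 5.61 on Casp1-/- replicate 2 and 4.96 and 4.98 on WT replicates 1 and 2, against 3.86 to 4.41 on the rest. That list passed in none of the contrasts below. Correlations between arrays ranged from 0.957 to 0.995, so no array was a copy of another.

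The arrays fell into 2 sets by the mean of 24 probe sets for poly-A spike-in controls, bacterial transcripts added to the RNA before labelling. The 3 Casp1-/- arrays (8.07, 7.73 and 7.51) and WT replicate 1 (7.80) were high. The other WT arrays (6.50, 6.19 and 5.76) and the ASC-/- arrays (6.27, 6.21 and 6.30) were low. The labels give no batch, so this division rests on the controls alone. The 3' minus 5' signal of actin, which rises as RNA shortens, was 0.98, 0.82 and 0.84 in Casp1-/-, 1.05, 0.91, 0.53 and 0.46 in WT replicates 1 to 4, and 0.59, 0.54 and 0.67 in ASC-/-. With the spike-in batch as a block, the Casp1-/- contrast rests on WT replicate 1 alone and the ASC-/- contrast on the remaining WT arrays. Blocked values are given beside the results for the lists and for part of the genes.

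The first comparison asked what loss of ASC did to the tissue. Pycard itself lay at background in ASC-/- fat, at 3.40 ± 0.27 (SD, n = 3) against 9.82 ± 0.62 (SD, n = 4) in WT (adjusted p = 1.98e-05). Only 6 of 17097 genes were past the threshold, 3 higher and 3 lower, and Pycard was 1 of them. Gdpd3, an enzyme that forms lysophosphatidic acid, rose 32.6-fold, from 5.59 ± 0.16 to 10.62 ± 0.19 (adjusted p = 6.76e-07). Ide, which degrades insulin, rose by 1.02 ± 0.086 (SE, adjusted p = 0.00314), and Wdfy1, an adaptor of Toll-like receptor signalling, by 1.45 ± 0.14 (SE, adjusted p = 0.0101). Dock2, which drives migration of leukocytes, fell 6.31-fold to 6.92 ± 0.054 from 9.58 ± 0.63 (adjusted p = 0.0147), and Slx1b, a subunit of a DNA repair nuclease, was 3.60 ± 0.21 against 4.82 ± 0.15 (adjusted p = 0.0353). Both of these means lay within the range of the background controls, and the other probe sets of Slx1b changed by -0.060 and -0.25. In all 6 the ASC-/- arrays did not overlap the WT arrays. Over all genes, 545 did not overlap (3.19%, where chance gives 5.71%).

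With the block the log2 changes were -6.66 for Pycard, 4.98 for Gdpd3, 1.07 for Ide, 1.46 for Wdfy1 and -2.90 for Dock2, all past the threshold, while Slx1b (-1.15) was not. The count dropped to 3 without ASC-/- replicate 1 or without ASC-/- replicate 3, and Pycard, Gdpd3 and Ide passed without any single array. Wdfy1 missed the threshold without ASC-/- replicates 1 or 3 (range over all single arrays left out, 1.31 to 1.52). Dock2 missed it without any 1 of the ASC-/- arrays, Casp1-/- replicate 3 or WT replicates 2 or 4 (range -2.90 to -2.40), and Slx1b passed only with every array or without Casp1-/- replicates 1 or 2 (range -1.35 to -1.15). Gdpd3 and Slx1b lie 60 and 63 genes from Pycard on the same chromosome, and 2 of the 200 nearest genes were past the threshold against 3 of 16895 others (Fisher's exact p = 0.00133). Among the 100 nearest genes, 50 on each side as set in advance, 0 passed limma's threshold and 6 had an unadjusted p under 0.05. The mean absolute moderated statistic of these 100 was 0.882 against 0.713 over all genes (permutation p = 0.0123). Both Fisher's test and the permutation treat genes as independent, which they are not, so their p may be too small.

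**Figure D1:**
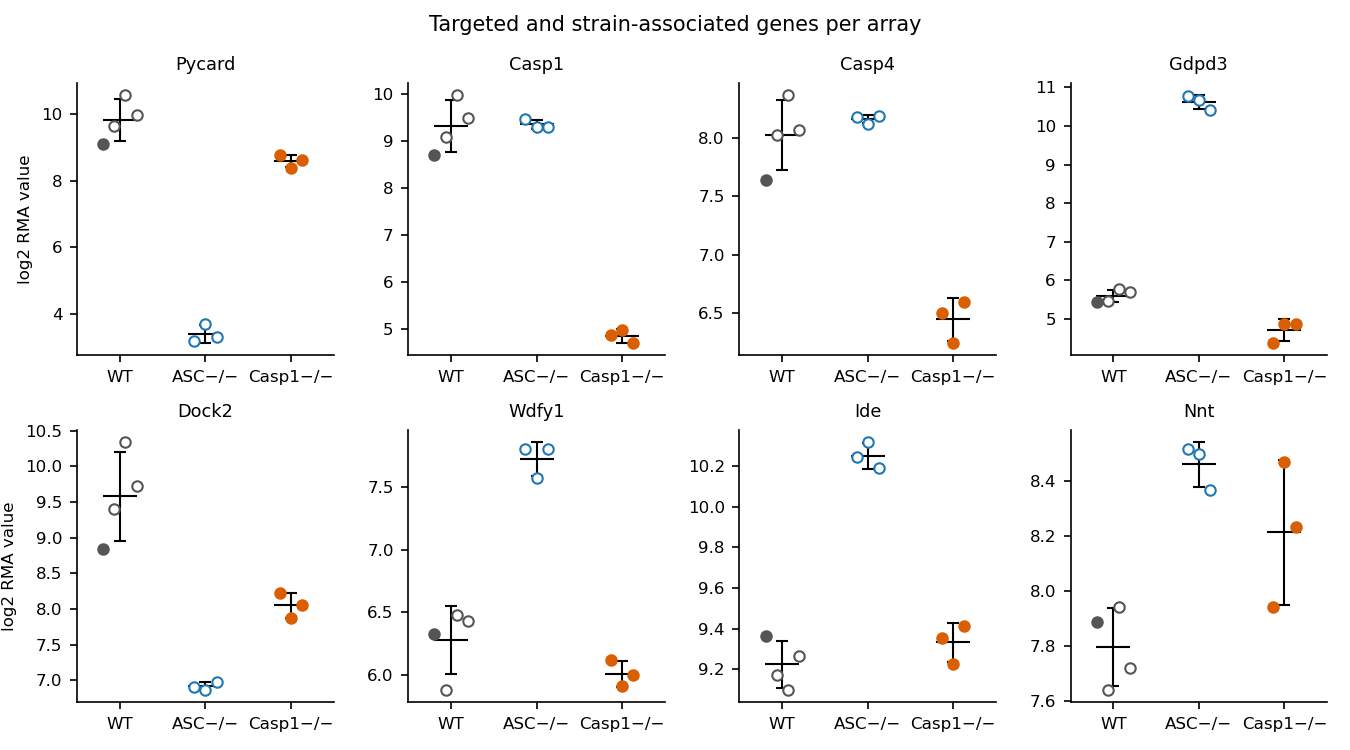
Log2 signal of 8 genes (vertical axis) on each array of the WT, ASC-/- and Casp1-/- groups (horizontal axis), with filled points for arrays with high and open points for arrays with low spike-in signal, and bars for the mean ± SD. Pycard lay at 3.40 in ASC-/- and Casp1 at 4.85 in Casp1-/-, against 9.82 and 9.32 in WT.

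Other genes of the inflammasome, of macrophages and of adipocytes that were fixed in advance missed the threshold in ASC-/- fat. Casp1 was 9.36 ± 0.095 against 9.32 ± 0.55 and Casp4 8.16 ± 0.036 against 8.02 ± 0.30. The macrophage marker Adgre1 was 11.21 ± 0.32 against 10.99 ± 0.73, the adipokine genes Lep and Adipoq 12.71 ± 0.14 against 12.47 ± 0.33 and 13.53 ± 0.058 against 13.51 ± 0.19, and the lipogenic enzyme Fasn 11.78 ± 0.24 against 11.65 ± 0.45. Il1b (3.94 and 3.98), Nlrp3 (4.47 and 4.34) and Tnf (4.66 and 4.54) lay within the range of the background controls in both groups. Itgax, a marker of inflammatory fat macrophages that lies 2 genes from Pycard, was 10.74 ± 0.43 against 9.89 ± 0.67, and the chemokine gene Ccl2 9.73 ± 0.23 against 9.15 ± 0.43. Neither passed. The substrain genes Nnt (0.66, blocked 0.69) and Entpd4 (-0.98, blocked -0.81) differed without overlap between the arrays but missed the threshold, with adjusted p = 0.667 and 0.573.

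By camera 9 lists were past the threshold in ASC-/- fat, though no member passed over all genes. The interferon-stimulated genes were lower as a group, with 20 of 21 members below WT and a median of -0.17 (adjusted p = 1.95e-09; adjusted p = 0.191 with an estimated correlation). Xaf1 (-0.39) and Oas2 (-0.42) are examples, and adjusted over the list alone 1 member fell. T cell and NK cell markers were lower too, with 16 of 22 below WT and a median of -0.19 (adjusted p = 7.22e-07; adjusted p = 0.191 with an estimated correlation). Adjusted over the list alone 3 fell, among them Cd3g (-0.69) and Cd3d (-0.71), and 1 rose, but several lay near background (Cd3g at 3.64 in ASC-/-). The mean of the T cell list was 4.20 to 4.24 on the ASC-/- arrays and 4.26 to 4.51 on the WT arrays. Both lie within the range of the background controls, so the size of its change is uncertain. Blocked medians of the interferon and T cell lists were -0.18 and -0.19. Oxidative phosphorylation (median -0.072, 50 of 51 below WT, adjusted p = 2.54e-07; adjusted p = 0.796 with an estimated correlation) and the citric acid cycle (-0.11, 19 of 20, adjusted p = 4.93e-04; adjusted p = 0.81 with an estimated correlation) shifted down by small amounts. Brown and beige adipocyte genes had a median of -0.23 (15 of 17 below WT, adjusted p = 8.53e-05; adjusted p = 0.44 with an estimated correlation), and Ppargc1b, a coactivator of mitochondrial genes, was 7.16 ± 0.021 against 7.63 ± 0.17. The mean of the list was 5.87, 5.55, 5.06 and 6.19 in WT replicates 1 to 4 and 5.23, 5.21 and 5.37 in ASC-/-, so WT replicate 3 lay below all ASC-/- arrays. The median was -0.20 without WT replicate 4 and -0.49 without WT replicate 3, both past the threshold.

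Higher as a group in ASC-/- were extracellular matrix genes (median 0.12, 27 of 31 above WT, adjusted p = 4.93e-04), red blood cell markers (0.21, 5 of 6, adjusted p = 0.00892), immediate early genes (0.14, 14 of 21, adjusted p = 0.0381) and endothelial markers (0.17, 14 of 18, adjusted p = 0.0406). With an estimated correlation these gave adjusted p = 0.477, 0.477, 0.747 and 0.927. The immediate early gene Ccn1 was 9.35 ± 0.62 against 8.27 ± 0.39. Adjusted over the list alone, 0 members of these 4 lists, of the energy lists or of the brown and beige list passed. With the block the matrix (0.084), immediate early (0.032) and citric acid cycle (-0.062) lists were no longer past the threshold, while 13 lists passed camera, pan-macrophage markers (-0.12) among them, and none of these with an estimated correlation (adjusted p = 0.0961 to 0.808). The endothelial list was lost without ASC-/- replicates 2 or 3 or WT replicates 2 or 3 (medians 0.089 to 0.17), the immediate early list without ASC-/- replicates 1 or 3 or WT replicates 1 or 2 (0.032 to 0.15), the matrix list without WT replicate 1 (0.084), the red blood cell list without WT replicate 3 (0.13), and the citric acid cycle without WT replicates 1 or 4 (-0.062 and -0.050). By fry 0 lists passed (adjusted p = 0.399 to 0.957). In limma 166 genes were higher and 176 lower at an unadjusted p under 0.05, together 2% of all genes, below the share of 0.05 that chance gives. Without WT replicate 3 the number of lists past camera's threshold was 18. The other 28 lists had adjusted p from 0.0545 to 0.978 by camera. For 2 of these, the progenitor and the pancreas markers, the test pointed down while median and mean were above 0.

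The second comparison asked what loss of caspase-1 did, and here the tissue differed broadly. Casp1 fell into the range of the background controls, to 4.85 ± 0.14 (SD, n = 3) from 9.32 ± 0.55 (SD, n = 4; adjusted p = 2.33e-04), and its neighbour Casp4, the caspase of the noncanonical inflammasome, fell 2.99-fold to 6.45 ± 0.18 (adjusted p = 0.00417). In all, 1397 genes passed, 737 higher and 660 lower, and of these 147 rose and 357 fell by more than 2-fold. Macrophage genes were among the losses. Adgre1, a surface protein of macrophages, fell 3.92-fold to 9.02 ± 0.17 (adjusted p = 0.0163), Cd68 4.33-fold, and Atp6v0d2, a proton pump subunit of lysosomes in lipid-laden macrophages, 8.85-fold to 8.03 ± 0.86 (adjusted p = 0.0112). With the block the log2 changes were -3.87 for Casp1 and -1.20 for Casp4, both past the threshold, and -1.23 for Adgre1, -1.26 for Cd68 and -2.22 for Atp6v0d2, which were not.

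Of 22 pan-macrophage markers 18 fell over all genes and 21 when adjusted over the list alone (median -1.44, camera adjusted p = 1.25e-17). Of 16 genes of lipid-associated macrophages, which form crowns around dying adipocytes, 14 fell, and 15 fell and 1 rose adjusted over the list alone (median -1.79, adjusted p = 4.05e-13). Examples are Nceh1 (5.69-fold lower), Slc37a2 (6.11-fold lower) and Itgax (3.44-fold lower), while the abundant Lgals3 fell 1.73-fold. Cell cycle genes moved alike, 16 of 28 falling over all genes and 27 adjusted over the list alone (median -1.08, adjusted p = 1.82e-19), with Cdk1 3.64-fold, Birc5 3.63-fold and Mki67 3.02-fold lower. Of 13 genes of MHC class II presentation 5 fell, 7 adjusted over the list alone (median -0.45, adjusted p = 1.99e-04), among them H2-DMb1 (2.47-fold) and the invariant chain Cd74 (1.89-fold). All 4 lists gave adjusted p = 0.459 with an estimated correlation and 0.0374 by fry. The falls with the block were 3.65-fold for Nceh1, 3.24-fold for Slc37a2, 1.92-fold for Itgax and 1.47-fold for Lgals3. They were 2.29-fold for Cdk1, 2.10-fold for Birc5, 1.975-fold for Mki67, 1.855-fold for H2-DMb1 and 1.19-fold for Cd74. Blocked medians of the lists were -0.69, -1.06, -0.52 and -0.12. The first 3 lists passed camera with the block (adjusted p = 0.819 for each with an estimated correlation), with 0 members past the threshold over all genes in any of them (adjusted over the list alone, 0, 7 and 5 fell), and the MHC list did not. The mean of the pan-macrophage markers was 9.47, 9.15 and 9.45 in Casp1-/- and 10.09 in WT replicate 1, the other high spike-in array, against 10.50, 11.50 and 11.06 in WT replicates 2 to 4.

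Not every macrophage gene was lower. The tissue-resident and alternatively activated macrophage genes had a median of 0.37 (16 genes, camera adjusted p = 0.81). The chemokine gene Ccl24 (1.09, adjusted p = 0.0195) and the lectin gene Mgl2 (1.32, adjusted p = 0.0333) rose, and Arg1 (-1.42, adjusted p = 0.0126), the arginine-degrading enzyme, and Clec10a (-0.92, adjusted p = 0.0288) fell. Adjusted over the list alone 6 rose and 4 fell. This list and these genes were taken up after their values had been seen. The blocked median was 0.22, with 0 members past the threshold in limma.

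**Figure D2:**
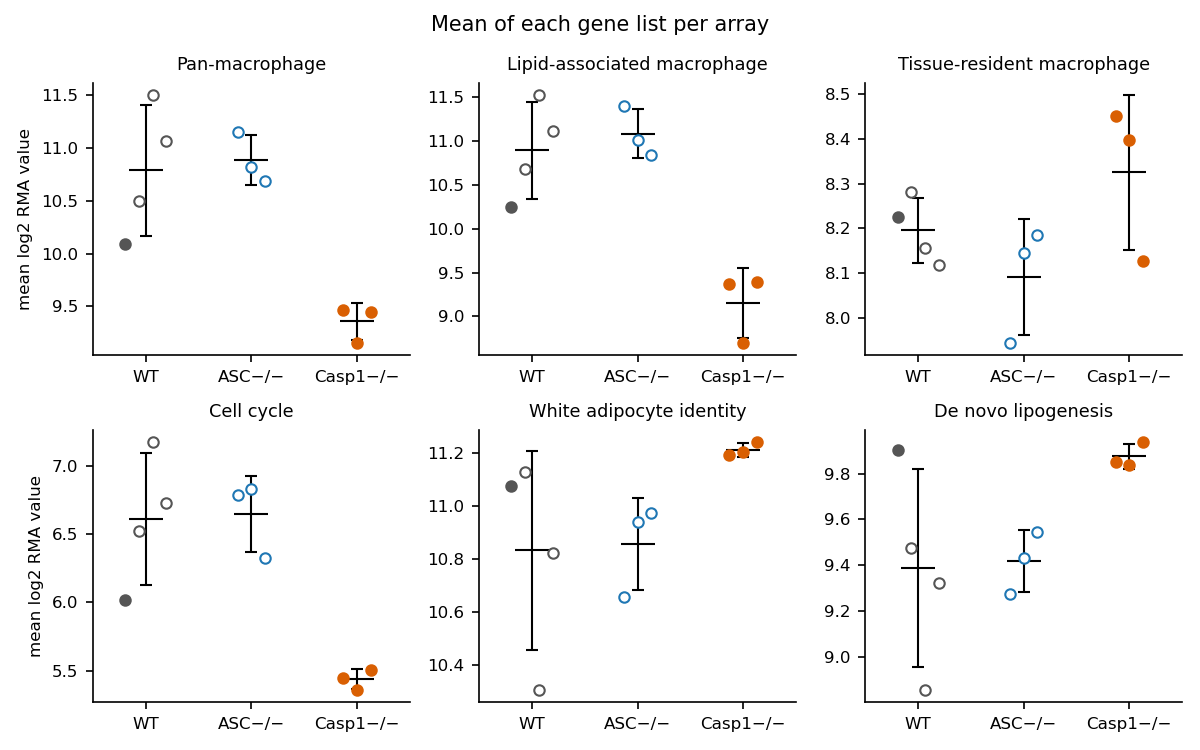
Mean log2 signal of the members of 6 gene lists (vertical axis) on each array of the WT, ASC-/- and Casp1-/- groups (horizontal axis), with filled points for high and open points for low spike-in arrays, and bars for the mean ± SD. The pan-macrophage means of the Casp1-/- arrays (9.15 to 9.47) lay below all WT arrays (10.09 to 11.50), with the high spike-in WT array the nearest.

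Inflammatory mediators, the remaining inflammasome genes and B cell markers were lower as lists, with few members past the threshold. Of 24 cytokine and chemokine genes 2 fell and 1 rose, the same adjusted over the list alone (median -0.14, adjusted p = 0.0234; adjusted p = 0.486 with an estimated correlation). Those that fell were Il1rn, which encodes the interleukin-1 receptor antagonist (6.16-fold), and Ccl9 (2.57-fold), while Tnf (4.33 ± 0.25 against 4.54 ± 0.26), Ccl2 (8.75 ± 0.36 against 9.15 ± 0.43) and Il1b (4.17 ± 0.14 against 3.98 ± 0.27) did not pass. Of 17 inflammasome genes other than the targets 3 fell, 5 adjusted over the list alone (median -0.15, adjusted p = 0.0061). These were Naip2 (3.42-fold), the ATP receptor P2rx7 (2.20-fold) and Il1rap (4.69 ± 0.19 against 5.37 ± 0.20), whereas Il18 (8.14 ± 0.32 against 7.99 ± 0.19) and Nlrp3 (4.24 ± 0.063 against 4.34 ± 0.13) did not pass. Pycard, not counted in the list, fell 2.35-fold (adjusted p = 0.038). Of 16 B cell and plasma cell markers 3 fell, 4 adjusted over the list alone (median -0.11, adjusted p = 0.0163): Cd72 (8.07-fold), Blnk (4.64-fold) and Tnfrsf13b (1.78-fold), the first pair of which macrophages also express. The inflammasome and B cell lists gave adjusted p = 0.459 with an estimated correlation. Blocked medians were 0.0042, -0.044 and -0.39, none past the threshold, and Pycard had -0.51 with the block, not past it either. The falls with the block were 2.88-fold for Il1rn, 1.85-fold for Ccl9, 2.07-fold for Naip2 and 1.69-fold for P2rx7. They were 3.77-fold for Cd72, 2.85-fold for Blnk and 1.32-fold for Tnfrsf13b, all smaller than without it. The cytokine list was lost without WT replicates 2 or 3 (medians -0.15 and -0.11) and the B cell list without Casp1-/- replicate 3 (0.024).

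Immediate early genes, matrix genes and the unfolded protein response were lower as lists. Of 21 immediate early genes 4 fell (median -0.26, adjusted p = 0.00553), with Atf3 6.95-fold, Egr2 4.29-fold and Fos 3.77-fold lower, and 6 fell and 1 rose adjusted over the list alone. Of 31 matrix genes 5 fell (median -0.30, adjusted p = 0.0061), among them the protease Mmp3 (4.03 ± 0.46 against 7.22 ± 1.38) and its inhibitor Timp1 (2.91-fold), and 11 fell and 3 rose adjusted over the list alone. Of 22 genes of the unfolded protein response 4 fell and 1 rose (median -0.075, adjusted p = 0.021), and 8 fell and 2 rose adjusted over the list alone. Those that fell were Atf3, Creld2 (1.59-fold), Manf (1.28-fold) and Dnajb9 (1.26-fold). All 3 gave adjusted p = 0.459 with an estimated correlation. Blocked medians were -0.22, -0.068 and -0.025, none past the threshold. The falls with the block were 3.51-fold for Atf3, 2.98-fold for Egr2, 2.45-fold for Fos and 2.13-fold for Timp1. They were 1.36-fold for Creld2, 1.20-fold for Manf and 1.30-fold for Dnajb9.

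Adipocyte genes went the other way. The 2 lists also moved against each other among the WT arrays. In WT replicates 1 to 4 the white adipocyte means were 11.08, 11.13, 10.31 and 10.82, and the pan-macrophage means 10.09, 10.50, 11.50 and 11.06. Pparg, the transcription factor that maintains fat cells, rose 1.84-fold to 11.27 ± 0.18 (adjusted p = 0.0234), the 1 of 22 white adipocyte genes that passed over all genes and also adjusted over the list alone (median 0.38, list adjusted p = 0.0163; adjusted p = 0.845 with an estimated correlation). The glucose transporter gene Slc2a4 was 9.47 ± 0.15 against 8.31 ± 0.84, Adipoq 13.72 ± 0.0088 against 13.51 ± 0.19 and Lep 12.78 ± 0.078 against 12.47 ± 0.33, none past the threshold. Of 17 genes of de novo lipogenesis 3 rose, 9 adjusted over the list alone (median 0.31, adjusted p = 0.0061; adjusted p = 0.807 with an estimated correlation). They were Acaca (2.22-fold) and Fasn (1.82-fold, adjusted p = 0.0461), which build fatty acids, and their regulator Mlxipl (2.21-fold). Of 18 genes of branched-chain amino acid breakdown 2 rose, 10 adjusted over the list alone (median 0.56, adjusted p = 8.64e-05; adjusted p = 0.736 with an estimated correlation), Hsd17b10 by 1.42-fold. Endothelial markers were higher with 0 of 18 past the threshold in limma by either adjustment (median 0.46, adjusted p = 0.021; adjusted p = 0.845 with an estimated correlation). Blocked medians of these 4 lists were 0.12, 0.17, 0.25 and 0.37, and none passed. Blocked changes were 0.95 for Pparg, 0.77 for Acaca and 0.46 for Fasn, none past the threshold. The white adipocyte list was lost without WT replicate 3 (median 0.17), and the endothelial list without Casp1-/- replicate 3 or WT replicates 2 or 3 (0.24, 0.36 and 0.42).

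Among the larger single rises in Casp1-/- were those of Csprs (5.76-fold) and Prkag3 (5.05-fold). The acute-phase gene Orm3 (6.96 ± 0.46 against 3.72 ± 0.40, adjusted p = 0.00339), Rnase2a, an eosinophil-type ribonuclease (7.20 ± 0.96 against 3.94 ± 1.20), Adamtsl2 (7.13 ± 0.50 against 4.75 ± 0.32) and Folh1 (7.17 ± 0.23 against 4.80 ± 0.91) rose from WT means within the range of the background controls. Among the falls, Zranb3 (5.38 ± 0.90 against 8.75 ± 0.86), Rgs1 (8.81-fold), a regulator of chemokine receptors, and Hpgds (4.57 ± 0.13 against 7.64 ± 1.38), a prostaglandin D synthase, stood beside Mmp3, Atp6v0d2 and Cd72. Blocked log2 changes were 3.53 for Rnase2a, 3.58 for Orm3, 3.16 for Csprs, 1.83 for Folh1 and 2.03 for Prkag3, of which Orm3 alone passed, Adamtsl2 missed the threshold with the block (adjusted p = 0.0524), and the values were -2.46, -1.94 and -1.55 for the first 3 falls, none past the threshold. Dock2 fell by 1.53 (adjusted p = 0.0191), but was not past the threshold with the block (-0.79, adjusted p = 0.331), while Ide (0.11), Wdfy1 (-0.27), Entpd4 (0.26) and Nnt (0.42) did not pass. Of the 57 genes within 50 places of Casp1 8 passed, among them Casp4, Mmp3 and Mmp12 (mean absolute statistic 1.98 against 1.67, permutation p = 0.0903). Within 20 places the permutation p was 0.00629 (1e+05 resamples, mean 2.41), and within 100 it was 0.247. These tests permuted genes, which are not independent, so their p may be too small.

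The count for Casp1-/- moved with single arrays and with the batch. It was 64 without Casp1-/- replicate 2, 271 without Casp1-/- replicate 3, 308 without Casp1-/- replicate 1, 346 without WT replicate 4, 752 without ASC-/- replicate 2, 918 without ASC-/- replicate 3 and 3018 without WT replicate 1. With the spike-in block 120 passed, 29 higher and 91 lower, and in the 4 high spike-in arrays alone 226. All 1397 genes had the same sign with the block, with a median ratio of 0.721 to the change without it, and 28 were past the threshold in both fits. Of these 22 rose and 6 fell, and the fallers were Casp1, Casp4, Adam12 (-1.52, blocked -1.94), Crybg1, Pawr and Apoc4. The rises included, beside Orm3, the homeobox genes Hoxc5 (1.84, blocked 1.84) and Hoxc4 (1.52, blocked 1.61), and Axin2 (1.62, blocked 1.83), Gli2 (1.45, blocked 1.62) and Smad7 (1.46, blocked 1.64), genes of Wnt, hedgehog and transforming growth factor signalling. These names were chosen after their values were seen. Arrays did not overlap in 1393 of the 1397 genes, which largely gives their shared sign with the block. Over all genes 4220 (24.7%) did not overlap, where chance gives 5.71%. By camera 14 lists passed without and 5 with the block, the latter being the macrophage and cell cycle lists above together with interferon-stimulated genes (blocked median -0.22, unblocked -0.059 with adjusted p = 0.227) and cholesterol synthesis (blocked -0.28, unblocked 0.032 with adjusted p = 0.955). With the block none of these 5 passed with an estimated correlation (adjusted p = 0.819 to 0.866) or by fry (adjusted p = 0.511 to 0.72), and no member of the 14 lists was past the threshold over all genes. By fry 5 and with an estimated correlation 0 lists passed, with 2789 genes higher and 1934 lower at an unadjusted p under 0.05 in limma. The other 23 lists had adjusted p of 0.146 to 0.955, and in 7 of them median, mean and test differed in sign, as for the expansion markers (median 0.31, mean -0.088).

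The third comparison set ASC-/- directly against Casp1-/-, since separate contrasts with WT do not show that the null genotypes differ. All ASC-/- arrays were low and all Casp1-/- arrays high in spike-in signal, so genotype and batch cannot be told apart in it. With the block it becomes the difference between the blocked contrasts of each null genotype with WT, of which that of Casp1-/- rests on WT replicate 1 alone. The arrays of the null genotypes differed in 1264 genes, 658 higher and 606 lower in ASC-/-, macrophage genes among them. Adgre1 was 11.21 ± 0.32 (SD, n = 3) against 9.02 ± 0.17 (SD, n = 3), 4.56-fold higher in ASC-/- (adjusted p = 0.0142), and Itgax was 6.20-fold higher (adjusted p = 0.0106). Rgs1 (12.9-fold) and Zranb3 (9.05 ± 0.46 against 5.38 ± 0.90) were higher too. So were Gdpd3 (10.62 ± 0.19 against 4.70 ± 0.29), Mmp3 (7.66 ± 0.21 against 4.03 ± 0.46), the aminopeptidase gene Anpep (7.72 ± 0.42 against 4.35 ± 0.39) and Hpgds (7.93 ± 0.52 against 4.57 ± 0.13), whose Casp1-/- means lay within the range of the background controls. Lower in ASC-/- were Rnase2a (3.34 ± 0.031 against 7.20 ± 0.96) and Orm3 (3.94 ± 0.41 against 6.96 ± 0.46), both within that range in ASC-/-, and Angptl8 (6.32-fold), Mogat1 (5.66-fold), Cd209d (5.37-fold) and Syt12 (by 2.32 on the log2 scale), Angptl8 and Mogat1 being genes of triglyceride storage. Pycard (3.40 ± 0.27 against 8.59 ± 0.19) was lower and Casp1 (9.36 ± 0.095 against 4.85 ± 0.14) higher, and Ccl2 (9.73 ± 0.23 against 8.75 ± 0.36) missed the threshold with adjusted p = 0.0522.

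By list, 16 of 22 pan-macrophage markers (median 1.56, adjusted p = 5.44e-18), 15 of 16 lipid-associated macrophage genes (2.06, adjusted p = 8.67e-14) and 16 of 28 cell cycle genes (1.20, adjusted p = 8.17e-19) were higher in ASC-/-, and 22, 15 and 28 when adjusted over the list alone, where 1 lipid-associated gene was lower. So were 5 of 13 MHC class II genes (0.49, adjusted p = 2.41e-04; 7 adjusted over the list alone), 8 of 31 matrix genes (0.38, adjusted p = 3.40e-05; 13), 6 of 21 immediate early genes (0.33, adjusted p = 1.06e-04; 9), 3 of 17 inflammasome genes (0.21, adjusted p = 0.00872; 5) and 5 of 22 genes of the unfolded protein response (0.11, adjusted p = 0.0322; 9). In the last list 1 gene was lower over all genes and 2 adjusted over the list alone, and among the immediate early genes 1 was lower by that adjustment. Lower in ASC-/- were 4 of 18 genes of branched-chain amino acid breakdown (median -0.59, adjusted p = 1.41e-05; 14 adjusted over the list alone), 1 of 17 lipogenic genes (-0.26, adjusted p = 0.00905; 6) and 1 of 22 white adipocyte genes (-0.31, adjusted p = 0.0408; 1). Oxidative phosphorylation (-0.16, adjusted p = 4.42e-04; 0), the citric acid cycle (-0.27, adjusted p = 0.00617; 6) and mesothelial markers (-0.84, adjusted p = 0.0344; 0) were lower as lists with no member past the threshold over all genes. With an estimated correlation these 14 lists gave adjusted p = 0.438 to 0.846, and by fry 7 passed.

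With the spike-in block 63 genes differed, 55 higher and 8 lower in ASC-/-, and 13 of the 1264 were among them. Blocked medians were 0.59 for the pan-macrophage, 1.09 for the lipid-associated macrophage and 0.44 for the cell cycle list, which passed camera together with T cell markers (-0.26) and cholesterol synthesis (0.46), while the other 11 lists of the 14 did not. With the block none of the 5 passed with an estimated correlation (adjusted p = 0.959 to 0.977) or by fry (adjusted p = 0.289 to 0.919). No member of the 14 lists was past the threshold over all genes with the block. Blocked changes were 1.21 for Adgre1, 1.52 for Itgax, 2.09 for Rgs1, 2.45 for Zranb3, 2.08 for Mmp3, 0.71 for Anpep, 1.33 for Hpgds, -4.22 for Rnase2a, -2.05 for Angptl8, -1.57 for Mogat1, -1.63 for Cd209d and -0.73 for Syt12, none past the threshold. Gdpd3 (5.72), Orm3 (-3.48), Pycard (-6.16) and Casp1 (3.70) stayed past it. The count was 47 without ASC-/- replicate 1, 154 without ASC-/- replicate 2, 664 without ASC-/- replicate 3, 352, 68 and 326 without Casp1-/- replicates 1, 2 and 3, 1972 without WT replicate 1 and 2615 without WT replicate 3. With the actin covariate it was 231. After centring of each array on its median 40.4% of the genes past the threshold were higher in ASC-/-, against 52.1% before. The mesothelial list was lost without ASC-/- replicate 1, Casp1-/- replicate 2 or WT replicate 3 (medians -0.56, -0.42 and -0.84), the white adipocyte list without ASC-/- replicate 1, Casp1-/- replicates 2 or 3 or WT replicate 4 (-0.19 to -0.31), and the unfolded protein response without ASC-/- replicate 3 (0.13). All 1264 genes were without overlap between the arrays, as were 6904 (40.4%) of all genes, where chance gives 10%.

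**Figure D3:**
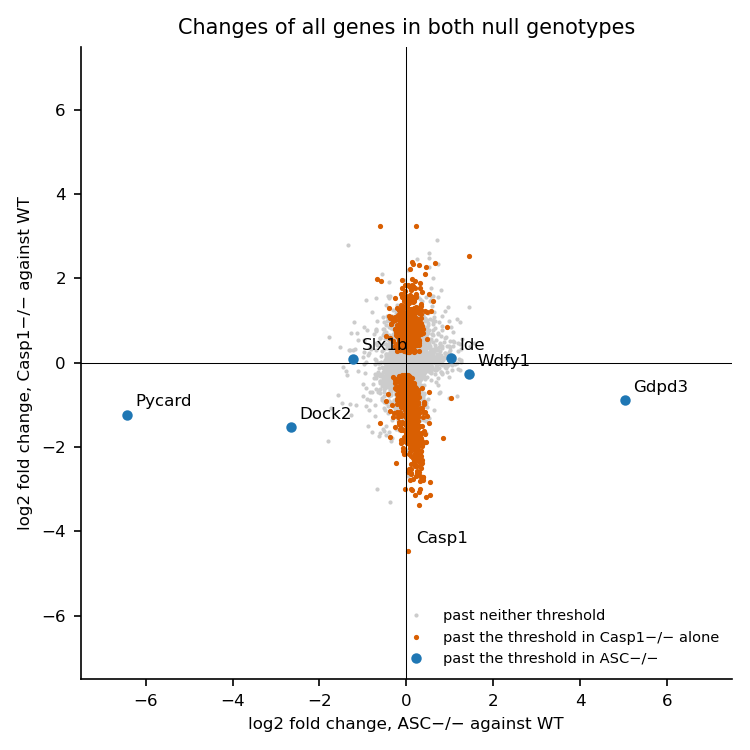
Log2 change in Casp1-/- against WT (vertical axis) over the log2 change in ASC-/- against WT (horizontal axis) for each of 17097 genes, with blue points for genes past the threshold in ASC-/-, orange for those past it in Casp1-/- alone and grey for the rest. The correlation across genes was 0.051, and Pycard and Dock2 were lower in both.

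The fourth comparison asked what the null genotypes had in common, as the mean of both against WT. Past the threshold were 6 genes. Pycard (-3.83, adjusted p = 4.92e-04), Casp1 (-2.22, adjusted p = 0.00937) and Gdpd3 (2.07, adjusted p = 4.92e-04) each differed strongly in a single genotype. In Casp1-/- Gdpd3 went the other way (-0.89), to a mean within the range of the background controls. Dock2 was lower in both null genotypes (-2.09, adjusted p = 0.0337), with all 6 null arrays below all 4 WT arrays, though the fall in Casp1-/- was not past the threshold with the block. Its fall in Casp1-/- without the block (-1.53) was close to the median of the pan-macrophage markers (-1.44), so it did not stand out from the macrophage genes. Hoxc4 (0.73) and Tulp3 (0.59) were past the threshold too (adjusted p = 0.0397 for each), but through Casp1-/- alone. Hoxc4 was 6.63 in ASC-/-, 8.21 in Casp1-/- and 6.68 in WT, and Tulp3 6.46, 7.26 and 6.27 (adjusted p = 1 for each in ASC-/- against WT). The null arrays did not overlap the WT arrays in 128 genes (0.749%, where chance gives 0.952%). With the block 31 genes passed, 8 higher and 23 lower, the 6 among them. The count was 2 without ASC-/- replicates 2 or 3, Casp1-/- replicates 1 or 3 or WT replicate 4, and 3 without Casp1-/- replicate 2.

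In that contrast 16 lists passed camera with 0 members past the threshold in limma, where 1148 genes were higher and 772 lower at an unadjusted p under 0.05, and 0 lists passed with an estimated correlation (adjusted p = 0.452 to 0.759) or by fry (0.267 to 0.518). The cell cycle list (median -0.53, adjusted p = 1.61e-16), pan-macrophage markers (-0.66, adjusted p = 4.33e-14) and lipid-associated macrophage genes (-0.76, adjusted p = 1.84e-10) were the lowest, and adjusted over the list alone 12, 11 and 9 of their members fell. In ASC-/- against WT the medians of these 3 lists were 0.051, 0.11 and 0.15, so without the block the fall of the mean came from Casp1-/-. With the block those medians were -0.16, -0.12 and -0.043, the first pair past camera's threshold (adjusted p = 1.54e-04 and 0.0457) but not with an estimated correlation (adjusted p = 0.68 and 0.808). Blocked medians of the mean were -0.36, -0.43 and -0.52. The other 13 had adjusted p from 6.31e-04 to 0.0402 and medians from -0.20 to 0.31, and 10 lists passed with the block, 8 of these 16 among them, but none of the 10 with an estimated correlation (adjusted p = 0.549 to 0.933). Without WT replicate 3 the branched-chain (0.022), lipogenesis (0.13), white adipocyte (0.033), inflammasome (-0.047), cytokine (-0.017), red blood cell (0.18) and unfolded protein (-0.020) lists were lost. Without WT replicate 1 the interferon (-0.045), red blood cell (0.26) and brown and beige (-0.11) lists were lost, and without WT replicate 2 the endothelial (0.24), cytokine (-0.074), brown and beige (-0.23) and unfolded protein (-0.030) lists. The brown and beige and unfolded protein lists were also lost without WT replicate 4 (-0.046 and -0.040), ASC-/- replicate 2 (-0.23 and -0.030) or Casp1-/- replicate 3 (-0.17 and -0.025). Further losses were those of the endothelial list without Casp1-/- replicate 3 (0.20), the cytokine list without ASC-/- replicate 2 (-0.055), the red blood cell list without Casp1-/- replicate 2 (0.26), and the inflammasome (-0.068), red blood cell (0.26) and brown and beige lists without ASC-/- replicate 1, the median of the last ranging from -0.38 to -0.046 over all arrays left out singly.

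Across the 17097 genes the log2 changes of the null genotypes were almost unrelated (Pearson's r = 0.051, Spearman's rho = 0.097, covariance 0.0043), and genes are not independent replicates. Because both contrasts share the WT arrays, simulated groups without any change gave a mean r of 0.40, with most of 1000 simulations between -0.48 and 0.93, and a mean covariance of 0.022. When the WT arrays were split so that none was shared, r was -0.58, 0.0047, -0.33, 0.072, -0.22 and 0.15, and with each null genotype against the WT arrays of its own spike-in batch it was -0.10. The signs were the same in 54.3% of genes, against 64.3% in the simulations. Of the 1397 genes past the threshold in Casp1-/-, 661 (47.3%) had the same sign in ASC-/-. Among the falls 2 were shared, Dock2 and Pycard, where 0.116 were expected by n1 × n2 / N, and among the rises 0, where 0.129 were expected by that product from limma's calls. The product treats the contrasts as independent although they share the WT arrays, so it is not the overlap without any change. Pycard is the targeted gene of ASC-/-, and with the block neither gene was past the threshold in Casp1-/-. Without it their falls in Casp1-/-, -1.53 for Dock2 and -1.23 for Pycard, were close to the pan-macrophage median there (-1.44).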

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

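All tests of explanations below were chosen only after the results had been seen. In 9 of 158 named genes and 0 of 37 lists 1 WT array lay far from the other WT arrays, by a rule that marks about 1 in 20 groups by chance. These were Ucp1 (9.30) and Ccn1 (8.84) in WT replicate 4, Dio2 (5.18) in WT replicate 1, and Dbt (7.97), Elovl6 (6.94), Mmut (9.17), Mogat1 (5.24), Ndufa5 (9.70) and Slc2a4 (7.06) in WT replicate 3, all 6 of these lower than in the other WT arrays. The 1264 genes that differed between the null genotypes were marked because a change in 1 null genotype was not shared by the other, though these genotypes also differ in spike-in batch. Among 16139 probe sets without a single gene symbol, left out of the gene tests, 2 passed in ASC-/- and 425 in Casp1-/-, 180 higher and 245 lower.

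Regrouping the same arrays asked whether chance can be excluded. In ASC-/- against WT 2 of 35 splits, the real one included, gave at least the real 6 genes, so chance was not excluded for the count. That count includes the deleted gene Pycard and says nothing on single genes. The highest other gave 627 and set WT replicates 3 and 4 and ASC-/- replicate 1 against the rest. These had the highest pan-macrophage means of that comparison (11.50, 11.06 and 11.15), and low spike-in arrays lay on both sides. So many more calls than the real ones point to structure of the samples that runs with the macrophage markers. In Casp1-/- against WT 2 of 35 gave at least the real 1397. The highest other, with 2234, set WT replicates 2 to 4 against the rest, and chance was not excluded. That split follows the spike-in batch and also the pan-macrophage means (10.50, 11.50 and 11.06 against 9.15 to 10.09), which cannot be told apart there. Between the null genotypes 10 splits are too few (1 of 10, the real one with 1264, the highest other with 0). For the mean of both 4 of 100 gave at least 6 genes, and with the deleted genes Pycard and Casp1 left out 4 of 100 gave at least the remaining 4. That share by itself would exclude chance. The highest other gave 2839 and set WT replicates 3 and 4 and ASC-/- replicates 1 and 2 against the rest. These had the highest pan-macrophage means of all arrays (10.82 to 11.50), and low spike-in arrays again lay on both sides. This too is structure of the samples, so the count does not measure a change shared by the null genotypes. Of the remaining 4 genes, Hoxc4 and Tulp3 came from Casp1-/- alone, and Gdpd3 rose in ASC-/- but had -0.89 in Casp1-/-. Dock2 was lower in both, though in Casp1-/- its fall (-1.53) was close to the pan-macrophage median (-1.44) and not past the threshold with the block. Over all genes 0.749% were without overlap where chance gives 0.952%.

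The first pattern is the set of 6 genes past the threshold in ASC-/-. DNA of another strain carried along with the Pycard allele may account for 2 of them, Gdpd3 and Slx1b, which lie among the 200 nearest genes (Fisher's exact p = 0.00133), though Slx1b was near background. Among the 100 nearest genes, 50 on each side as set in advance, 0 passed, so that p rests on the wider window. It also counts the 2 genes as independent, and may be too small. Whether the substrain background away from Pycard accounts for others stays open. A first count of substrain genes included Ide and Wdfy1, themselves among the 6, and was replaced. Of the 2 fixed in advance and outside the 6, Nnt and Entpd4, 2 had an unadjusted p under 0.05, as 2% of all genes had (exact binomial p = 4.00e-04), but 2 genes are too few to decide. Fewer macrophages were excluded as the cause of the Dock2 fall of -2.66. Their marker means were 11.15, 10.82 and 10.69 in ASC-/- and 10.09, 10.50, 11.50 and 11.06 in WT. The lowest median of the macrophage, T cell and B cell lists, 60 genes, was -0.19, and each median lay further above the Dock2 change than the spread of its members. The T cell list, however, had array means of 4.20 to 4.51, within the range of the background controls, and could not show such a fall. The B cell list had WT means of 5.6 to 5.8, little above that range, so T and B cells stay open. This test replaced one of the lowest single marker, Jchain (-1.73 ± 0.57, SE), which was too variable to decide.

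The second pattern is the broad change in Casp1-/-. The labelling batch could not be told apart from the genotype. With the spike-in block the changes kept a median ratio of 0.721, but only 1 WT array lay in that batch, and the shared sign of genes whose arrays do not overlap is largely given by their selection. Fewer macrophages of every kind were not excluded. The 16 tissue-resident macrophage genes had a median of 0.37 against -1.44 for 22 pan-macrophage markers, a distance of 1.82 beside a joint SD of the members of 0.98 (0.90 beside 0.70 with the block), but members went both ways. Over the 35 splits of the arrays the difference of the list means had an exact permutation p = 0.0571. This test replaced one that permuted genes, which are not independent. A genotype effect and fewer lipid-associated macrophages were not tested.

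The third pattern is Ucp1 in WT replicate 4. The first test counted brown adipocyte genes with their highest value on that array, 4 of 16, and left a probe fault undecided (exact binomial p = 0.0684), so another was chosen after it. By that test 3 of 16, Cidea (9.02), Cox7a1 (8.33) and Cpt1b (7.61), lay above all other arrays by more than their range, as 36 of all genes did (exact binomial p = 5.12e-06), which excludes a fault of the Ucp1 probe set alone. Brown or beige adipocytes in that tissue piece might explain it, as 3 of 4 genes checked, Cidea, Cox7a1 and Cox8b (10.63), were highest there. Elovl3 (4.23) and Dio2 (3.97) were not, but both lay within the range of the background controls on that array and cannot decide, so this stays open.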

How the results depend on the processing

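The spike-in block, the actin covariate, the macrophage covariate and the fits of only the low or only the high spike-in arrays were chosen after the data had been seen, and the cause of the differences below was not tested. Signal over background limits Il1b, Nlrp3 and Tnf, whose changes are small differences between values near that of the controls. Below, a value is called weaker or stronger where it crossed the threshold and turned where its sign changed, whatever its size. All others are called the same, among them genes past the threshold in neither fit. For single genes the alternatives chosen in advance left 4698 values the same, made 571 weaker and 112 stronger and turned 39. Those added later left 536 the same, made 185 weaker and 6 stronger and turned 24. For the lists past camera's threshold 881 planned values were the same and 179 weaker, and of the added ones 76 were the same, 50 weaker and 3 turned. With the spike-in block 120 genes passed in Casp1-/-, 63 between the null genotypes and 31 in their mean, with 5, 5 and 10 lists. All ASC-/- arrays were low and all Casp1-/- arrays high, so the block compares each null genotype only with WT arrays of its own set. Changes in the low or high arrays alone, and in ASC-/- without WT replicate 1, equal the blocked ones by construction and are no separate check. In ASC-/- the list medians that turned with the block included pan-macrophage (-0.12), cell cycle (-0.16) and lipid-associated macrophage genes (-0.043). Named genes that turned with it in ASC-/- were Adgre1 (-0.027), Casp1 (-0.17) and Slc2a4 (0.070), the same in the low spike-in arrays alone. In Casp1-/- they were Ccl2 (0.022), Entpd4 (-0.23), Ide (-0.033) and Tnf (0.12), the same in the high spike-in arrays alone, where 226 genes passed and Casp4 (-1.20) missed the threshold. Between the null genotypes Tnf (-0.11), Lep (0.11), Ucp1 (-0.93) and the tests of de novo lipogenesis (median -0.088), oxidative phosphorylation (-0.016) and white adipocyte genes (-0.0099) turned, and in the mean of both Tnf (0.066) and Nlrp3 (-0.044). The agreement was -0.10 with WT arrays of the same batch, and -0.58, -0.33 and -0.22 in 3 of the WT splits. With the actin covariate Adgre1 (-0.087), Casp1 (-0.18) and Slc2a4 (0.11) turned in ASC-/-, with 14 lists past the threshold there, and Lep (0.14) and Ucp1 (-1.22) turned between the null genotypes, with 231 genes past it. With the macrophage covariate 16 lists passed in ASC-/-, 3 genes in Casp1-/- and 6 between the null genotypes. The sign changed for 1 of 58 named genes in ASC-/-, 19 of 81 in Casp1-/-, 19 of 83 between the null genotypes and 15 of 84 in their mean. Array weights gave 2998 genes in Casp1-/- and 3428 between the null genotypes, and turned Casp1 (-0.055) and Il1b (0.013) in ASC-/-. Fits of only the compared groups gave 3, 469 and 3248 genes in ASC-/-, in Casp1-/- and between them. Median centring turned Adipoq ASC-/- against WT (-0.0078) and Il18 mean of both null genotypes against WT (-0.0063), quantile normalization turned Il18 (-0.00079) and Nlrp3 (-0.026) in that mean, and the mean over probe sets turned Ide in Casp1-/- (-0.036). With an estimated correlation 0 lists passed camera in any contrast, and by fry 0 passed in ASC-/-, 5 in Casp1-/-, 7 between the null genotypes and 0 in their mean. With 20 neighbours on each side the mean statistic next to Casp1 was 2.41. Over arrays left out singly, the number of genes ranged from 3 to 6 in ASC-/-, 64 to 3018 in Casp1-/-, 47 to 2615 between them and 2 to 5 in their mean, and the number of lists in ASC-/- from 10 to 18. In ASC-/- the change of Adgre1 ranged from -0.027 to 0.49, Adipoq from -0.071 to 0.073, Casp1 from -0.17 to 0.26, Fasn from -0.070 to 0.27, Il18 from -0.26 to 0.0048, Il1b from -0.13 to 0.056 and Slc2a4 from -0.53 to 0.070. In Casp1-/- Il18 ranged from -0.023 to 0.29. Between the null genotypes Lep ranged from -0.12 to 0.0038 and Ucp1 from -0.042 to 0.13. In the mean of both Ccl2 ranged from -0.057 to 0.24, Il18 from -0.083 to 0.092, Il1b from -0.0080 to 0.18, Nlrp3 from -0.031 to 0.076 and Tnf from -0.16 to 0.044.

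With the replicate number as a block, which leaves fewer degrees of freedom and takes WT replicate 4 out of the contrasts because no null array has its number, 3 genes passed in ASC-/-, 9 in Casp1-/-, 19 between the null genotypes and 0 in their mean. Without WT replicate 4 alone 346 had passed in Casp1-/-. All 1397 genes kept their direction in Casp1-/-, which is largely given by their selection, as arrays did not overlap in 1393 of them. Casp4 (-1.57) missed the threshold there, while Ccl2 (-0.011) and Nlrp3 (-0.031) turned in the mean of both. The numbers do not pair the arrays. Correlations of the deviations from the group means ranged from -0.26 to 0.19 for arrays of the same number, and WT replicate 2 correlated best with ASC-/- replicate 3 (0.39).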

Other observations

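A few clock genes differed in Casp1-/- fat from WT and from ASC-/-, but their list did not pass. In Casp1-/- the clock activator Npas2 fell by 1.42 (adjusted p = 0.00817), and Cry2 (0.88, adjusted p = 0.03), Tef (0.64, adjusted p = 0.0449) and Bhlhe40 (0.81, adjusted p = 0.046) rose. Over all genes 3 of 18 rose and 1 fell, 5 and 1 adjusted over the list alone (camera adjusted p = 0.16, median 0.29, blocked 0.45). In ASC-/- against Casp1-/- 2 were higher, Npas2 (1.94, adjusted p = 0.00346) and Arntl (0.93, adjusted p = 0.0364), and 4 lower, with Hlf (-1.44, adjusted p = 0.0123) and Tef (-1.11, adjusted p = 0.0123) among them. With the block 0 members passed in limma over all genes. The time of day at which the tissue was taken is not given in the sources used here. These genes were chosen after their values were seen.

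Single genes of glucose use and of the response to low oxygen rose in Casp1-/-: Vegfa (1.22, adjusted p = 0.0148), Hk2 (1.06, adjusted p = 0.0299), P4ha2 (0.70, adjusted p = 0.0265) and Pfkp (0.35, adjusted p = 0.0407). Neither list passed camera (adjusted p = 0.81 for 15 glycolysis genes and 0.637 for 18 hypoxia genes). Adjusted over the list alone 4 glycolysis genes rose and 1 fell, Pgk1, and 5 hypoxia genes rose and 3 fell, Pgk1, Car9 and Angptl4. With the block 0 members of either list passed in limma. These genes were chosen after their values were seen.

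With the spike-in block 92 genes passed in Casp1-/- that had not passed without it. In 85 of these WT replicate 1 lay above all 9 other arrays and in 7 below them. Cartpt (8.42, highest other array 3.27), the muscle genes Myocd (6.49, highest other 3.99), Ckm (6.57, highest other 4.19) and Des (9.46, highest other 7.62), and Pax8 (6.71, highest other 4.50) are examples, chosen after their values were seen. Their passing thus rests on that array, and why it differed was not tested.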
